A study of Mus musculus with 8 samples.

How the data were processed

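RNA from mouse spermatids was sequenced in 8 libraries that form 4 groups of 2. Round spermatids are the early haploid male germ cells, and elongating spermatids are the later stage at which the nucleus condenses and the tail grows. Each stage was labelled either wild type (WT) or conditional knockout of Carm1. CARM1 is an arginine methyltransferase that acts as a transcriptional coactivator. Per the labels' protocols, cells of each sample came from 8 testes of C57BL/6 mice, were separated by centrifugal elutriation, and gave poly A libraries made with a TruSeq kit that does not mark strand. The labels number the libraries 1 and 2 within each group. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. The chi-square of recovered reads between the libraries of a group was 1.37 per gene in round WT, 2.31 in round KO-labelled, 1.59 in elongating WT and 1.57 in elongating KO-labelled cells, so they differed by more than sampling noise and were counted separately.

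The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10, HTSeq 0.6.0 and DESeq 1.16.0, with the mouse builds mm10 and GRCm38. The role and order of these tools, the strand setting of the counting and the gene annotation are not given in the sources used here. The deposited table holds a normalized signal per gene and library, which by its steps is the count of whole reads divided by a size factor of the authors. Dividing each column by its smallest value above 0 gave whole numbers for 100% of values at a tolerance of 1e-06. The table has 16349 genes, and the lowest total of recovered reads over the 8 libraries was 15. Recovered reads ranged from 17190962 to 23526694 per library. The size factors that the values imply were 1.57 and 1.65 in round WT, 1.57 and 1.77 in round KO-labelled, 0.776 and 0.693 in elongating WT and 0.516 and 0.530 in elongating KO-labelled libraries. The 50 most abundant genes took 10.1% and 10.1% of reads in round WT, 10.2% and 10.3% in round KO-labelled, 31.9% and 31.9% in elongating WT and 34.9% and 34.8% in elongating KO-labelled libraries. Symbols were matched to GENCODE M21, an annotation of GRCm38, by name or through RefSeq, and 16311 genes received a position.

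Because the deposited values are normalized and not raw counts, the test was limma 3.58.1 (R 4.3.3) with an empirical Bayes trend on log2(value + 1), as fixed before the data were examined for this case. Genes with a value of at least 10 in at least 2 libraries were tested, which left 15685. All 8 libraries entered one model with 4 group means and 4 residual degrees of freedom. The contrasts were KO-labelled against WT in round and in elongating spermatids, the difference between these effects, and elongating against round spermatids in each genotype. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and rose or fell means called with that direction in the group named first. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Some groups of a named knockout contrast within a stage held at most 3 recovered reads. For these the ratio of reads with its exact 95% interval is given. At 0 reads the ratio to a floor of 3 counts over the group stands beside the lower limit of that interval. Such intervals and floors cover counting error only.

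Before the data were examined, 27 gene lists were fixed: the CREM axis and its cofactors, CREM-dependent spermatid genes, arginine methyltransferases, transcription regulators of spermatids, histone variants and the histone-to-protamine exchange, acrosome, flagellum, ion channels and transporters, germ-cell glycolysis, testis-specific serine kinases and signalling, chromatoid body, mRNA storage and translation, ubiquitin and proteasome, X- and Y-linked multicopy genes, CARM1 partners and substrates, p53 targets, dissociation and heat stress, cytosolic ribosomal proteins, mitochondrially encoded transcripts, and markers of spermatocytes, spermatogonia, Sertoli, Leydig, peritubular and vascular, macrophage, red blood and epididymal cells. Some genes stand in several lists, so the list results are not independent. Most CREM-dependent genes are also in another list. Prm1, Prm2, Tnp1 and Tnp2 are shared with the histone list, and Gapdhs with the flagellum and glycolysis lists. Lists with at least 3 tested genes, 25 of them, were tested with camera at a preset correlation of 0.01. The same test with an estimated correlation, and fry, were run beside it. The version with an estimated correlation uses only the 4 residual degrees of freedom, which raises its p-values. Fry tests a list on its own, while camera compares it with the other genes. Named genes followed a rule fixed at the same time: Carm1; the 10 genes with the largest rise and the 10 with the largest fall in each knockout contrast among called genes with no overlap between libraries a mean of at least 100 in the higher group and a symbol other than a numbered gene model; the CREM axis; and up to 4 called members of every other list by p, or the 2 with the highest mean where none was called. The difference between stages and the WT stage contrast used 6 genes per direction, with up to 3 per list for the latter. The text names only part of the genes that met the rule, a choice that was not fixed beforehand, and the values of the others are not reported here, though all stay in the tests and counts.

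On data simulated from the real means at a dispersion of 0.002, the round contrast over 15366 genes recovered 40% of 50 genes changed 1.25-fold, 80% at 1.5-fold, 90% at 2-fold and 98% at 4-fold, with 12 false calls. In the elongating contrast, where nothing was changed, it made 0 calls. Each simulated gene had the same mean share of reads in all 8 libraries and the same dispersion, and changed genes came from above a minimum mean. The simulation thus held no difference between stages, so these rates may not carry over to the real libraries.

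The alternatives fixed beforehand were TMM factors, no filter, a mean of at least 50, DESeq2 1.42.0 on recovered reads, a fit on the 4 libraries of a contrast, the replicate number as a block, each library left out, pseudocounts of 0.5 and 10, and library sizes without the 50 most abundant genes. After seeing the data, edgeR 4.0.16 (quasi-likelihood test on recovered reads) and total-count scaling were added. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Genes on overlapping or antisense loci and genes with near-identical copies are uncertain, since reads can be assigned to the wrong one.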

Results

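Poly A RNA was measured in round and elongating mouse spermatids, each labelled WT or Carm1 knockout, with 2 libraries in each of 4 groups. Recovered reads came to 17190962 and 18143970 in round WT, 18318721 and 20720496 in round KO-labelled, 23410938 and 21090436 in elongating WT and 23317319 and 23526694 in elongating KO-labelled libraries. Levels below are normalised read counts, given as mean ± SD with n = 2 libraries per group unless stated. Adjusted p-values come from limma with Benjamini-Hochberg adjustment. The design asks which genes differ upon loss of Carm1 at each stage, and the study's title names the axis of p300, ACT and CREM. CREM is the transcription factor that drives many postmeiotic genes, and ACT, encoded by Fhl5, is its testis coactivator.

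Carm1 (chromosome 9, 21546894 to 21592623, GRCm38) measured 1668 ± 26.2 in round WT and 1259 ± 119 in round KO-labelled libraries, a log2 fold change of -0.41 (SE 0.05, adjusted p = 3.8e-05). In elongating spermatids it went the other way, from 4421 ± 159 in WT to 8075 ± 116 in KO-labelled libraries, a log2 fold change of 0.87 (SE 0.05, adjusted p = 2.7e-09). This rise goes against the knockout label, so the libraries are called KO-labelled throughout, and every direction given for elongating spermatids rests on labels that the target gene did not bear out. With library sizes computed without the 50 most abundant genes the elongating value was 0.37, and with total-count scaling 0.31. Gene totals cannot show whether the deleted exons are absent.

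**Figure D1:**
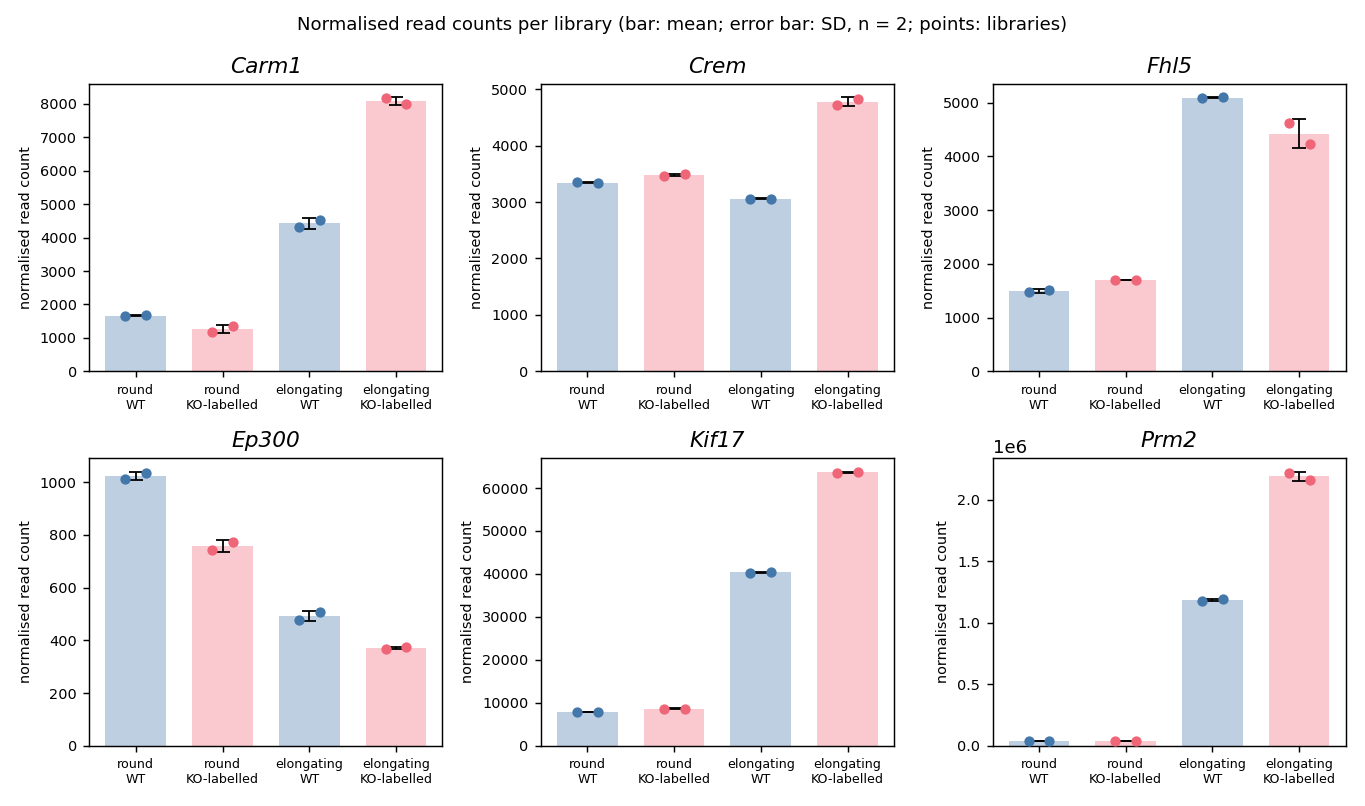
Normalised read counts (y axis, starting at 0) of 6 genes in the 4 groups (x axis); bars are means, error bars SD with n = 2 and points libraries. Carm1 was lower in round and higher in elongating KO-labelled libraries, and Ep300 was lower at both stages.

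In round spermatids 3041 genes rose and 1977 fell in the KO-labelled libraries, of 15685 tested, and 492 and 437 of these changed over 2-fold. Lpo, the gene of lactoperoxidase (chromosome 11, 87806428 to 87828289), went from 1.23 ± 0.834 to 396 ± 28.7, and Ptchd3 from 284 ± 6.51 to 5631 ± 3.51 (log2 fold change 4.31, SE 0.06, adjusted p = 2.6e-15). Vnn1 had 1 recovered read in WT and 437 in KO-labelled libraries, a ratio of 421 (95% interval 75.1 to 16660), and Adgrg7 1 and 384, a ratio of 370 (66.0 to 14644). Gfap, Slc26a10, the dynein gene Dnah11, Cyp2c55, Stat2 and Fcgr3 also rose, by log2 4.87, 4.11, 3.68, 3.58, 3.42 and 3.13. Among genes that fell, Tas1r1, a taste receptor gene (chromosome 4, 152027914 to 152038568), went from 343 ± 12.4 to 1.55 ± 1.40 and Aldh1l1, a folate enzyme gene, from 898 ± 12.2 to 11.2 ± 2.42. Zfp93, Cpn1, Fxyd2, Myo7a, Cdca7l, Wwtr1 and Map4k1 had log2 fold changes of -4.05, -3.96, -3.01, -2.55, -2.43, -2.40 and -2.36. Slfn5os had 327 recovered reads in WT and 2 in KO-labelled libraries, a ratio of 170 (46.6 to 1408), but it is an antisense gene and the kit does not mark strand. Dnah11 and Cdca7l overlap on chromosome 12, so their reads are uncertain too. Under library sizes without the 50 most abundant genes the split was 2174 up and 2999 down, and with total-count scaling 2190 and 3044, so the excess of rises depends on the scaling.

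Of the 11 measured genes of the CREM axis, 6 rose and 1 fell in round spermatids, by small amounts. The list did not pass camera (adjusted p = 0.17, and adjusted p = 0.38 with an estimated correlation) but passed fry (adjusted p = 0.017). Crem itself measured 3342 ± 7.5 and 3482 ± 20.2 (log2 fold change 0.06, adjusted p = 0.22). Fhl5 rose by 0.18, Fhl4 by 0.34, Crebbp by 0.24, the kinesin gene Kif17 by 0.13, Atf1 by 0.18 and Gtf2a1l by 0.11, while Ep300, which encodes p300, fell by 0.44 (SE 0.06, adjusted p = 7.4e-05). Of the 6 rises, only that of Fhl4 stayed past the threshold with total-count scaling. The calls also ended without round WT replicate 1 for Fhl5 (adjusted p = 0.062), without round WT replicate 2 for Atf1 (0.099), and without either of these for Crebbp (0.082 and 0.099) and Gtf2a1l (0.11 and 0.12); leaving out round KO-labelled replicate 2 ended those of Atf1 (0.055), Crebbp (0.14) and Gtf2a1l (0.054), and leaving out replicate 1 that of Gtf2a1l (0.097). Creb1, Taf7l and Tbpl1 had log2 fold changes of -0.06, -0.15 and 0.11 and did not pass. Of the CREM-dependent genes, 11 of 16 rose and 2 fell (camera adjusted p = 0.0039, median log2 0.12), with Gapdhs at 0.32, Tnp2 at 0.32, Ldhc at 0.26 and Akap4 at 0.18. This call was lost with an estimated correlation (adjusted p = 0.38), and total-count scaling left 4 rises and 2 falls.

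Acrosome genes rose in 14 of 28 cases with 0 falls, Cylc1 and Spaca3 both by 0.46 (camera adjusted p = 0.0039). Flagellum genes rose in 24 of 43 and fell in 5 (0.00067), among them the axonemal dynein genes Dnah2, Dnah1 and Dnah8 at 0.47, 0.43 and 0.32. Germ-cell glycolysis genes rose in 12 of 23 and fell in 2 (0.0039), with Slc2a3 at 0.55 and Tpi1 at 0.42. Cytosolic ribosomal protein genes, many of which have near-identical pseudogenes, rose in 14 of 34 and fell in 2 (0.0039). With an estimated correlation these 4 adjusted p-values were 0.24, 0.38, 0.31 and 0.16. Total-count scaling gave 6 rises and 3 falls, 17 and 10, 11 and 6, and 10 and 5. Adjusted over the list alone, the CREM-dependent, acrosome, flagellum, glycolysis and ribosomal lists had 12, 15, 26, 13 and 15 rises and 2, 0, 5, 3 and 2 falls.

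Genes induced by cell dissociation and heat rose in 12 of 20 cases and fell in 1 (camera adjusted p = 0.00067, adjusted p = 0.16 with an estimated correlation; adjusted over the list alone 13 and 2). Atf3 had 0 recovered reads in WT and 58 in KO-labelled libraries, 18.6-fold higher against the floor (exact 95% interval from 14.7). Junb and Fosb rose by log2 1.59 and 1.29. Markers of Sertoli cells, the somatic nurse cells, fell in 12 of 23 cases and rose in 1 (0.00029, adjusted p = 0.16 with an estimated correlation; list alone 13 and 1). Macrophage and leukocyte markers rose in 7 of 15 with 0 falls (0.013, adjusted p = 0.24 with an estimated correlation; list alone 8 and 1). Total-count scaling gave 12 and 4 for the stress list, 1 and 13 for Sertoli and 6 and 1 for macrophage markers. Most of these markers were low in round WT cells, where 3 of 23 Sertoli and 1 of 15 macrophage markers, Aif1, had a mean of at least 100. Clu, a Sertoli marker, measured 120 ± 6.73 against 70.9 ± 4.93 and Csf1r, a macrophage marker, 15.5 ± 1.21 against 31.0 ± 4.76.

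The other lists did not pass camera in round spermatids. Some passed fry, such as multicopy genes (fry adjusted p = 0.0030) and serine kinases and signalling (0.023). Others did not, such as the histone exchange (0.18) and p53 targets (0.52). Rises and falls were 1 and 1 of 8 for arginine methyltransferases, 5 and 1 of 17 for transcription regulators, 7 and 3 of 20 for the histone exchange, 4 and 3 of 16 for ion channels, 8 and 2 of 17 for serine kinases and signalling, 7 and 2 of 21 for the chromatoid body, 5 and 5 of 20 for mRNA storage, 6 and 1 of 21 for ubiquitin and proteasome genes and 3 and 0 of 9 for multicopy genes. They were 2 and 2 of 15 for CARM1 partners, 2 and 1 of 18 for p53 targets, 6 and 7 of 28 for spermatocyte, 3 and 0 of 20 for spermatogonia, 0 and 2 of 8 for Leydig, 6 and 3 of 19 for peritubular and vascular and 1 and 1 of 3 for epididymis markers. The red blood cell list had 2 measured genes, of which 0 were called, and 0 mitochondrially encoded transcripts were in the table. Among these lists H1fnt, a spermatid linker histone gene, fell by 0.42, the meiotic recombinase gene Dmc1 by 0.91 and the apoptosis gene Bbc3 by 1.51. Fbxo11 fell by 0.83 and was the only fall in the arginine methyltransferase list as fixed, so no Prmt gene of that list was called lower. Cypt3, a multicopy gene, rose by 0.79. Adjusted over the list alone, ion channels had 7 rises and 5 falls, the chromatoid body 7 and 3, CARM1 partners 3 and 3, spermatocyte markers 6 and 9, spermatogonia markers 0 and 0 and epididymis markers 2 and 1, and the other lists here the same counts. With total-count scaling the balance turned for transcription regulators (1 and 3), the histone exchange (3 and 5), ion channels (3 and 5), serine kinases (2 and 4), the chromatoid body (4 and 6), ubiquitin genes (2 and 5), p53 targets (1 and 2) and spermatogonia markers (0 and 1). Lists that were even became 1 and 6 for mRNA storage, 0 and 6 for CARM1 partners and 0 and 1 for arginine methyltransferases. For the mRNA storage and p53 lists the median was above 0 (0.04 and 0.05) while the mean (-0.07 and -0.03) and the test pointed down, for Leydig markers the test pointed down with a median of 0.24, and for epididymis markers the median was 0.09 and the mean -0.17.

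**Figure D2:**
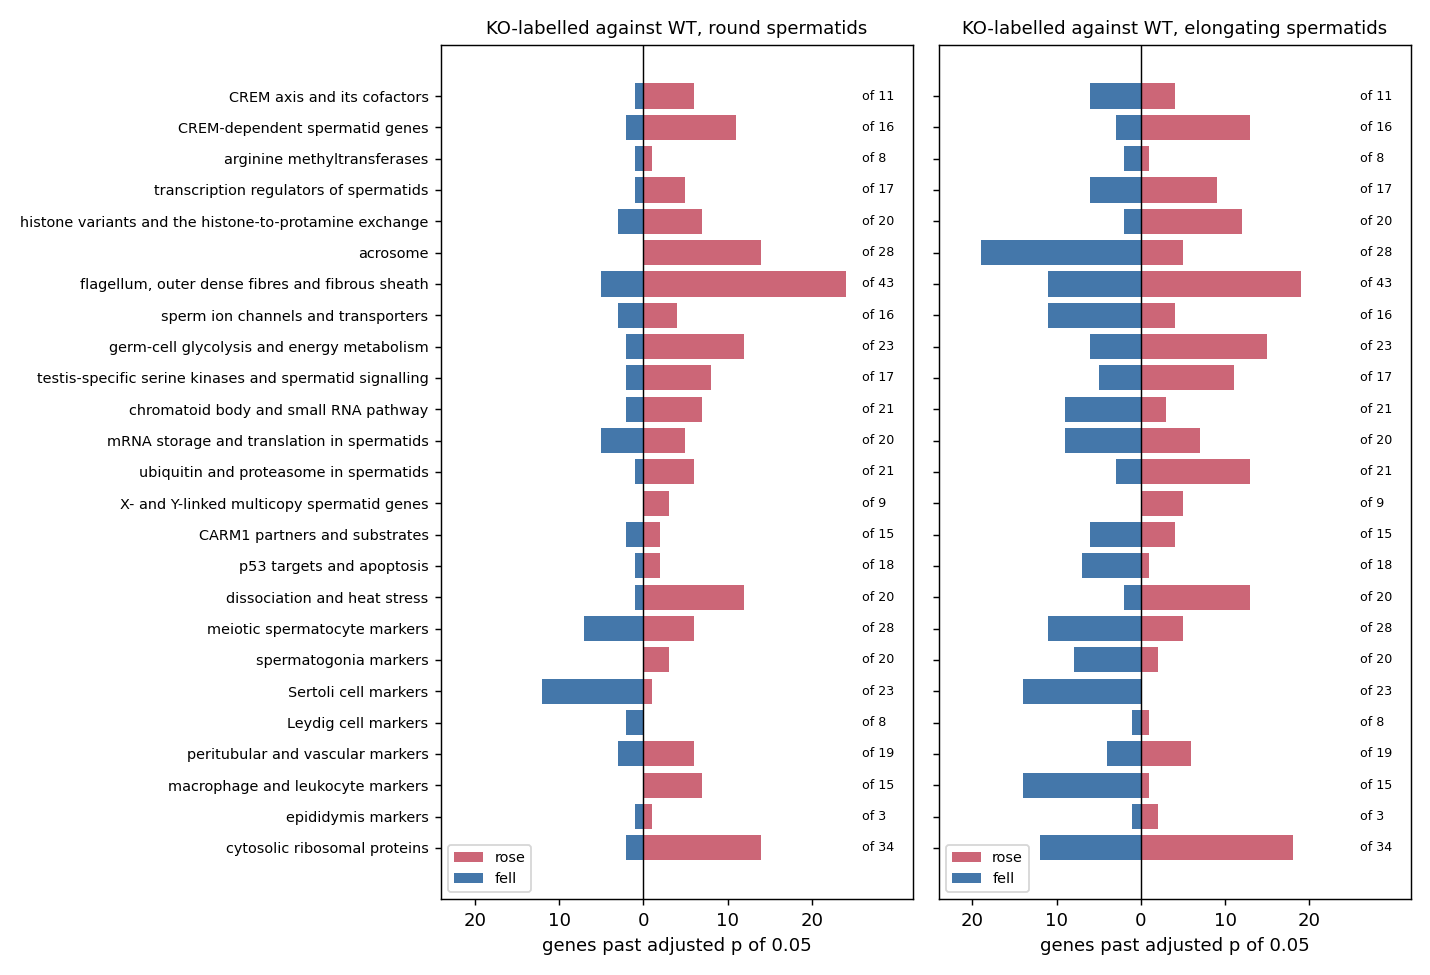
Number of genes in each list that rose (right) or fell (left) past an adjusted p of 0.05 in KO-labelled against WT libraries, with the number tested beside each bar, for round and elongating spermatids. Acrosome genes had 14 rises and 0 falls in round and 5 rises and 19 falls in elongating spermatids; with total-count scaling the round counts were 6 and 3 and the elongating counts 2 and 24.

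In elongating spermatids 4279 genes rose and 4348 fell in the KO-labelled libraries, and 954 and 1048 changed over 2-fold. Fut2, a fucosyltransferase gene (chromosome 7, 45648591 to 45666394), had 1 recovered read in WT and 126 in KO-labelled libraries, a ratio of 177 (95% interval 31.2 to 7044), and Lpo 2 and 118, a ratio of 82.9 (22.4 to 692). Slc26a10, Cyp2c55, Ankfn1, Klf1, Ptchd3, A1cf, Ears2 and Bloc1s6 rose by log2 5.53, 4.41, 4.28, 4.23, 4.04, 3.97, 3.70 and 3.59. Psg19 had 232 recovered reads in WT and 0 in KO-labelled libraries, 55.1-fold lower against the floor (exact 95% interval from 44.4). Slfn5os, antisense and uncertain, had 1411 and 1, a ratio of 1005 (180 to 39709). Dscaml1 went from 1470 ± 72.1 to 79.2 ± 18.7 and Slc41a3 from 3512 ± 8.57 to 232 ± 19.5, while Tas1r1, Aldh1l1, Ttc34, Cdca7l, Mpo and Ghr had log2 fold changes of -5.83, -3.71, -3.71, -3.67, -3.19 and -3.11. The split depends on scaling: without the 50 most abundant genes in the library sizes it was 1661 up and 9256 down, and with total-count scaling 1388 and 9839. The median log2 fold change of all genes was -0.07 as deposited, -0.56 and -0.62.

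Relative to the deposited scaling, Crem rose from 3056 ± 9.05 to 4781 ± 74.5 (log2 fold change 0.65, SE 0.03, adjusted p = 6.2e-10), and 0.08 with total-count scaling. Fhl4 rose by 0.62, Kif17 by 0.66 and Atf1 by 0.72. Fhl5 fell by 0.20, Ep300 by 0.40, Creb1 by 0.86, Taf7l by 0.27, Gtf2a1l by 0.29 and Tbpl1 by 0.85, and Crebbp measured -0.05 (adjusted p = 0.57). The fall of Taf7l did not pass with DESeq2, edgeR or the 4-library fit. As a list, 4 rose and 6 fell (camera adjusted p = 0.96, adjusted p = 0.96 with an estimated correlation, fry adjusted p = 0.0035), and 3 and 7 with total-count scaling. CREM-dependent genes rose in 13 of 16 cases and fell in 3 (camera adjusted p = 0.00018, median 0.63). Gapdhs rose by 0.95, the protamine gene Prm2 by 0.89, Akap4 by 0.88 and the transition protein gene Tnp1 by 0.81. This call was lost with an estimated correlation (adjusted p = 0.27), and total-count scaling left 7 rises and 5 falls.

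Acrosome genes fell in 19 of 28 cases and rose in 5 (camera adjusted p = 0.0016, adjusted p = 0.18 with an estimated correlation), with Spaca1 at -1.42, Spaca3 at -1.23 and Eqtn at -0.87, against 0.94 for Cylc2. Total-count scaling gave 24 falls and 2 rises. Genes of the histone-to-protamine exchange rose in 12 of 20 and fell in 2 (0.0016, adjusted p = 0.11 with an estimated correlation), Tnp2 by 0.85 and the proteasome activator gene Psme4 by 0.82, but with total-count scaling 7 rose and 7 fell. Glycolysis genes rose in 15 of 23 and fell in 6 (0.0025, adjusted p = 0.27 with an estimated correlation), and ubiquitin and proteasome genes rose in 13 of 21 and fell in 3 (0.0025, adjusted p = 0.25 with an estimated correlation), with Rnf19a at 1.03 and Cul3 at 0.76. With total-count scaling both turned, to 5 rises and 14 falls and to 5 rises and 13 falls. Adjusted over the list alone, the CREM-dependent, acrosome, histone, glycolysis and ubiquitin lists had 13, 5, 12, 15 and 13 rises and 3, 19, 2, 6 and 4 falls.

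Stress genes rose in 13 of 20 and fell in 2 (camera adjusted p = 0.0016, adjusted p = 0.11 with an estimated correlation; list alone 13 and 2), with Fosb at 2.59 and Egr1 at 1.90, and total-count scaling gave 7 and 7. Macrophage and leukocyte markers fell in 14 of 15 (0.0016, adjusted p = 0.11 with an estimated correlation; list alone 14 and 1), C1qc from 650 ± 6.26 to 166 ± 26.4 and Lyz2 from 338 ± 34.4 to 88.8 ± 7.68. The exception, Aif1, rose from 14128 ± 17.3 to 27312 ± 127, and it was already at 3077 ± 53.2 in round WT cells. Sertoli markers fell in 14 of 23 with 0 rises (0.0016, adjusted p = 0.11 with an estimated correlation; list alone 14 and 0), with Inha at -0.97 and Cst9 at -0.95. Peritubular and vascular markers rose in 6 of 19 and fell in 4, and total-count scaling gave 5 and 11. Sertoli markers took 0.0389% and 0.0388% of reads in WT and 0.0182% and 0.0183% in KO-labelled libraries.

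Other lists did not pass camera in elongating spermatids. Some passed fry, such as transcription regulators (fry adjusted p = 1.0e-04), serine kinases (1.3e-04) and p53 targets (0.00096). Others did not, such as ion channels (0.99), Leydig markers (0.32) and CARM1 partners (0.11). Rises and falls were 1 and 2 of 8 for arginine methyltransferases, 9 and 6 of 17 for transcription regulators, 19 and 11 of 43 for the flagellum, 4 and 11 of 16 for ion channels, 11 and 5 of 17 for serine kinases, 3 and 9 of 21 for the chromatoid body, 7 and 9 of 20 for mRNA storage, 5 and 0 of 9 for multicopy genes and 4 and 6 of 15 for CARM1 partners. They were 1 and 7 of 18 for p53 targets, 5 and 11 of 28 for spermatocyte, 2 and 8 of 20 for spermatogonia, 1 and 1 of 8 for Leydig and 2 and 1 of 3 for epididymis markers, 1 and 0 of 2 for red blood cell markers and 18 and 12 of 34 for ribosomal proteins, whose median of 0.18 and mean of -0.01 differ in sign, as do those of the epididymis list, 0.39 and -0.20. Adjusted over the list alone, the flagellum had 20 rises and 11 falls, mRNA storage 7 and 12 and CARM1 partners 4 and 7, and the other lists here the same counts. With total-count scaling the transcription regulators, flagellum, serine kinase and ribosomal lists turned to 6 and 9, 8 and 33, 3 and 11, and 3 and 25, and the red blood cell and epididymis lists to 0 and 2 and to 1 and 2. Counts were 0 and 6 for arginine methyltransferases, 2 and 14 for ion channels, 0 and 20 for the chromatoid body, 3 and 16 for mRNA storage, 1 and 0 for multicopy genes, 2 and 13 for CARM1 partners, 1 and 12 for p53 targets, 1 and 19 for spermatocyte, 1 and 13 for spermatogonia and 1 and 3 for Leydig markers. The ion channel genes Catsperg2 and Atp1a4 rose by 2.08 and 1.24 while Catsper2 fell by 0.90 and Slc9c1 by 0.69. Tdrd6 fell by 0.73, Ddx4 by 0.36, Pabpc1 by 0.68, Rps14 by 1.22, Prmt1 by 0.92, Mdm2 by 0.82 and the meiotic cyclin gene Ccna1 by 1.01, while the synaptonemal complex gene Syce2 rose by 0.78.

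Genes called at both stages were compared, since the group means of these contrasts share no library. Both contrasts use the same spread per gene, estimated from all 8 libraries, so their calls are not independent. The overlaps given for independent lists are thus a reference and no test. Of the genes that rose, 1911 did so at both stages, against 830 for independent lists of these sizes, and of those that fell 997 did so at both, against 548. A further 425 rose in round and fell in elongating spermatids, and 344 did the reverse. Of the 491 genes called and changed over 2-fold at both stages, 473 went in the same direction, 262 up and 211 down. Across genes, which are not independent replicates, the log2 fold changes of the stages correlated with r = 0.52 (Spearman's rho 0.39). The genes changed in the same direction at both stages split into 731 up and 2546 down with total-count scaling, and without the 50 most abundant genes 804 and 2401.

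**Figure D3:**
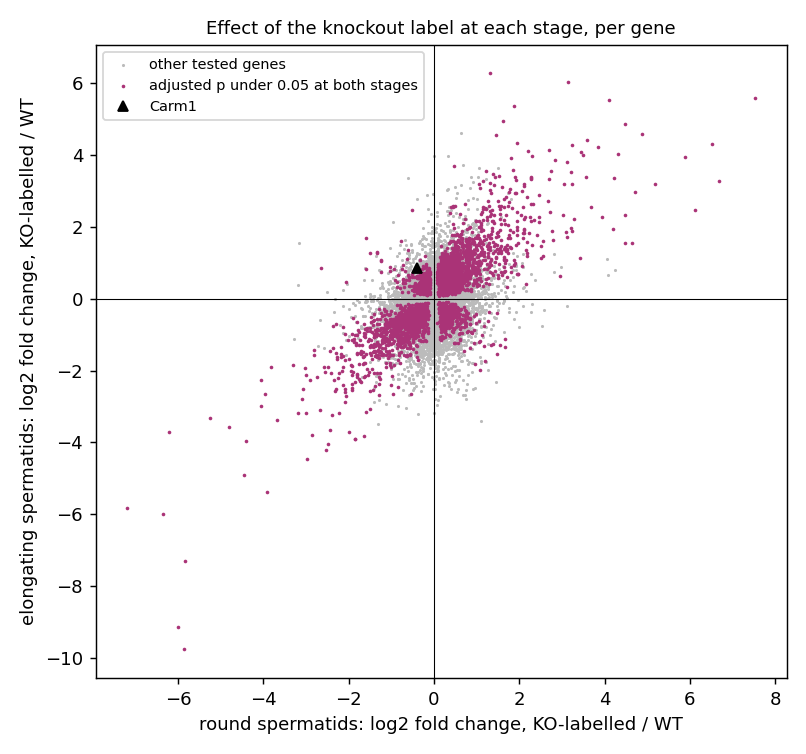
Log2 fold change of KO-labelled against WT libraries per gene in round (x axis) and elongating (y axis) spermatids, with genes called at both stages in purple and Carm1 as a triangle. Of the 491 genes called and changed over 2-fold at both stages, 473 lie in the quadrants of equal sign.

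The effect of the knockout label differed between stages for 5781 genes, higher in elongating spermatids for 3031 and lower for 2750. Ears2 differed by 3.23 and Gdpd5 by 2.99 upward, and C1qc by -3.04 and H2-Aa by -2.82 downward. The split was 853 and 7055 with total-count scaling, and 1069 and 6336 without the 50 most abundant genes. Acrosome genes had the difference in the negative direction in 19 of 28 cases (camera adjusted p = 2.6e-05, adjusted p = 0.13 with an estimated correlation).

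In WT cells, elongating against round spermatids gave 6548 rises and 6300 falls. CREM-dependent genes rose in 13 of 16 and fell in 3 (camera adjusted p = 6.6e-05, adjusted p = 0.20 with an estimated correlation), with Prm2 at 4.94, Odf1 at 4.56 and Gapdhs at 3.99, and spermatocyte markers fell in 24 of 28 and rose in 3 (2.2e-05, adjusted p = 0.044 with an estimated correlation), with Sycp1 at -2.83 and Sycp2 at -2.37. Oaz3 and Tssk6, postmeiotic genes, rose by 4.68 and 5.15. Acrosome genes fell in 22 of 28 and rose in 5 (0.00039, adjusted p = 0.13 with an estimated correlation), with Acr at -2.04, and chromatoid body genes fell in 16 of 21 (0.0031, adjusted p = 0.24 with an estimated correlation), with Tdrd6 at -2.30 and Ddx4 at -1.95. The fraction also carried somatic transcripts. Macrophage markers rose in 15 of 15 (camera adjusted p = 3.1e-06) and Sertoli markers in 23 of 23 (2e-06), both with adjusted p = 0.044 with an estimated correlation, with Cd74 going from 4.01 ± 1.17 to 4813 ± 30.7 and Clu from 120 ± 6.73 to 3699 ± 52.2. Peritubular and vascular markers rose in 16 of 19 (0.00026, adjusted p = 0.14 with an estimated correlation). Stress genes rose in 15 of 20 and fell in 5 (0.0072, adjusted p = 0.13 with an estimated correlation), and ion channel genes fell in 12 of 16 and rose in 4 (0.011, adjusted p = 0.24 with an estimated correlation). The histone exchange had 10 rises and 4 falls (0.025, adjusted p = 0.16 with an estimated correlation) and the ubiquitin list 14 and 4 (0.0072, adjusted p = 0.20 with an estimated correlation), which total-count scaling turned to 8 and 11 and to 7 and 11. Adjusted over the list alone, the counts of all lists in this contrast were the same. Ribosomal protein genes rose in 28 of 34 and fell in 5 (2.2e-05, adjusted p = 0.044 with an estimated correlation), but with total-count scaling 10 rose and 23 fell. The lists not named for this contrast did not pass camera. All genes split 3061 up and 10792 down with total-count scaling and 3910 and 9629 without the 50 most abundant genes. In KO-labelled cells the stage contrast gave 6677 rises and 6552 falls, 2611 and 11417 with total-count scaling, and 3472 and 10324 without the 50 most abundant genes.

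Among genes with a mean of at least 100 in round WT libraries, the effect of the knockout label in elongating spermatids was graded by the WT stage ratio. The 512 genes at least 4-fold higher in round cells had a median log2 fold change of -0.52, and the 375 genes at least 8-fold higher in elongating cells one of 0.60, as deposited. The matching medians in round spermatids were 0.01 and 0.04. The stage ratio and the elongating effect share the elongating WT libraries, which alone give a covariance of -0.007, against 0.444 observed (r = 0.49 across genes, simulated r = -0.50).

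**Figure D4:**
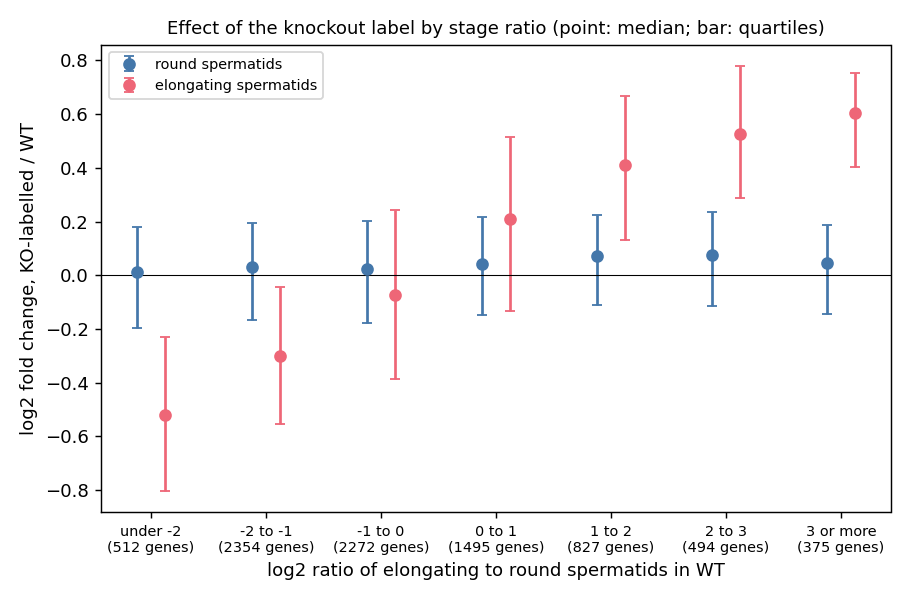
Median log2 fold change of KO-labelled against WT libraries (points, bars from the lower to the upper quartile of genes) by the log2 ratio of elongating to round spermatids in WT, for genes with a mean of at least 100 in round WT libraries. The elongating medians run from -0.52 to 0.60 while the round medians lie between 0.01 and 0.07, all with the deposited scaling. With the genes of each bin held fixed, another scaling moves all medians of a stage alike. It also shifts the stage ratios, and so which genes fall in each bin.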

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

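All tests of an explanation given here were chosen after the result was seen, except the test of gene length.

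Carm1 was lower in round and higher in elongating KO-labelled libraries, a difference between the effects of 1.28 on the log2 scale. Exchanged labels of the elongating libraries would turn the sign of other changes there too, but 93.1% of the genes changed over 4-fold in round spermatids had the same sign in elongating ones, while labels exchanged at both stages would leave this value as it is. The size factors of the authors do not account for the rise as a whole, since total-count scaling left 0.31. Reads from exons outside the deleted part cannot be told apart from reads of an intact gene, as 75.5% of the WT level was left in round spermatids and gene totals do not separate exons. A rise of Carm1 transcription in cells that lack the protein may be another explanation and was not tested.

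Among genes with a mean of at least 100 in round WT libraries, the medians of the elongating effect of the knockout label rose with the WT stage ratio (r = 0.49 across genes). Most Sertoli and macrophage markers lay below that level, and these lists went against the gradient: their median log2 ratios of elongating to round WT cells were 3.95 and 4.96, and their median effects in elongating spermatids -0.60 and -1.19. Whether the share of these cells changed too stays open. A factor per library, such as a scaling, moves all genes alike and cannot give such a gradient. Gene length is argued against, as the medians of stage-high and stage-low genes differed by 1.02 or more in each length group. Fewer round spermatids in the elongating KO-labelled libraries may be one source, but cannot be told apart from regulation by the genotype, since the fall of the 512 stage-low genes is itself the pattern. The effects of these genes had an SD of 0.49 against a median error of 0.11. This spread cannot decide, since a changed cell share would move each gene by the part of its reads from round cells. Effects of the genotype on single genes, untested here, would widen the spread too.

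The effect of the knockout label in elongating spermatids minus that in round spermatids was tested for each gene and list, and 5781 genes passed. Of the 190 named genes with both effects, 148 passed, a share raised by the choice of these genes by size or p in the same contrasts. Lists that differed upward were the CREM-dependent genes (camera adjusted p = 8.0e-05, median 0.55), the histone exchange (adjusted p = 0.0014, median 0.50) and ubiquitin and proteasome genes (adjusted p = 0.0032, median 0.27). Those that differed downward were the acrosome (adjusted p = 2.6e-05, median -0.39), the chromatoid body (adjusted p = 0.028, median -0.27) and macrophage markers (adjusted p = 2.6e-05, median -1.74). With an estimated correlation the adjusted p-values were 0.39, 0.13, 0.35, 0.13, 0.46 and 0.13, in this order. The CREM-dependent and histone lists share Prm1, Prm2, Tnp1 and Tnp2, and the histone and ubiquitin lists share Psme4. These upward differences are thus not independent of each other. The chromatoid body did not pass without elongating WT replicate 1 (adjusted p = 0.073) or elongating KO-labelled replicate 1 (adjusted p = 0.065). With total-count scaling the histone exchange had 6 rises and 3 falls, the CREM-dependent genes 6 and 5 and the ubiquitin list 6 and 10, so that the last turned.

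Differences of named genes that passed are given on the log2 scale as deposited, where a value above 0 means a higher effect in elongating spermatids and total-count scaling moves the median of all genes from -0.04 to -0.50 and turns the sign of 17 of these differences. Values of Vnn1, Adgrg7, Fut2, Lpo, Psg19, Atf3, Cd72 and Slfn5os are no measure of size, as a group held 3 recovered reads or fewer, and that of Slfn5os did not pass with DESeq2 (adjusted p = 0.28) or edgeR (0.24). Among genes with the largest rises and falls of a contrast, the difference was 4.96 for Fut2, 3.23 for Ears2, 3.20 for Ak5, 2.99 for Gdpd5, 2.63 for Ppp2r2c, 2.63 for Nkd1, 2.50 for Aldh1l1, 1.78 for Zfp93, 1.74 for Bloc1s6, 1.69 for A1cf, 1.60 for Map4k1, 1.42 for Slc26a10, 1.29 for Cpn1, 1.08 for Fxyd2, 0.51 for Myo7a and 0.34 for Wwtr1. Among other genes of this kind, the difference was -0.27 for Ptchd3, -1.13 for Dnah11, -1.24 for Cdca7l, -1.40 for Fcgr3, -1.48 for Psg19, -1.70 for Dscaml1, -1.71 for Ttc34, -1.95 for Lpo, -2.06 for Slc41a3, -2.20 for Adgrg7, -2.28 for Cd74, -2.29 for Stat2, -2.82 for H2-Aa, -2.89 for Cd72, -3.01 for Tgfbr2, -3.04 for C1qc, -3.14 for Slfn5os and -3.41 for Vnn1. For the CREM axis, the difference was 0.59 for Crem, 0.54 for Atf1, 0.53 for Kif17, 0.29 for Fhl4, -0.29 for Crebbp, -0.39 for Fhl5, -0.40 for Gtf2a1l, -0.79 for Creb1 and -0.96 for Tbpl1. Within the CREM-dependent genes, the difference was 0.78 for Prm2, 0.78 for Tnp1, 0.69 for Akap4, 0.64 for Gapdhs, 0.54 for Tnp2 and -0.14 for Ldhc. Regarding arginine methyltransferases, the difference was -0.89 for Prmt1. For transcription regulators, the difference was 0.77 for Tcfl5, 0.73 for Sox30, 0.71 for Rfx2, 0.62 for Spz1, 0.55 for Brdt, 0.32 for Rfx4 and 0.28 for Kdm3a. Within the histone exchange, the difference was 0.72 for H1fnt, 0.70 for Psme4 and -0.33 for H3f3a. Regarding the acrosome, the difference was 0.92 for Cylc2, 0.38 for Cylc1, -0.32 for Spata16, -0.76 for Prss21, -0.96 for Eqtn, -1.37 for Spaca1 and -1.69 for Spaca3. For the flagellum, the difference was 0.76 for Odf2, -0.22 for Dnah2, -0.31 for Dnah1 and -0.35 for Dnah8. Within ion channels, the difference was 1.65 for Catsperg2, 0.93 for Atp1a4, 0.51 for Adcy10, -0.56 for Slc9c1, -0.75 for Catsper2 and -0.88 for Slc9b1.

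Regarding glycolysis, the difference was 0.59 for Hk1, 0.45 for Tpi1, 0.41 for Aldoart2, 0.32 for Pgk2 and -0.89 for Slc2a3. For the serine kinases, the difference was 0.99 for Prkar2a, 0.89 for Akap1, 0.88 for Ppp1cc and 0.50 for Tssk3. Within the chromatoid body, the difference was 0.45 for Papolb, -0.15 for Mael, -0.30 for Tdrd1, -0.43 for Gtsf1, -0.51 for Ddx4, -0.71 for Tdrd6 and -0.80 for Tdrd7. Regarding mRNA storage, the difference was 0.64 for Eif4g3, 0.50 for Ybx2 and -0.76 for Pabpc1. For ubiquitin and proteasome, the difference was 0.73 for Rnf19a, 0.73 for Cul3 and 0.72 for Ube2j1. Within the list of X- and Y-linked multicopy genes, as fixed, the difference was 1.04 for Usp9y. Regarding CARM1 partners, the difference was 1.11 for Elavl4, 0.86 for Gps2 and 0.23 for Ncoa2. For p53 targets, the difference was 1.64 for Bbc3, -0.54 for Bcl2l1, -0.82 for Mdm2 and -1.41 for Ccng1. Within the stress genes, the difference was 1.30 for Fosb, 1.248 for Egr1, 0.47 for Dnajb1, -0.92 for Junb, -1.04 for Fos and -2.24 for Atf3. Regarding spermatocyte markers, the difference was 0.96 for Dmc1, 0.54 for Syce2, 0.52 for Syce1, -0.35 for Stag3, -0.70 for Rec8 and -1.10 for Ccna1. For spermatogonia markers, the difference was 1.14 for Sohlh2, -0.60 for Uchl1, -0.79 for Dmrt1, -1.44 for Stra8 and -2.34 for Sall4. Within Sertoli markers, the difference was 0.93 for Aard, 0.43 for Clu and -0.90 for Inha. Regarding Leydig markers, the difference was -0.87 for Fdx1. For peritubular and vascular markers, the difference was 2.38 for Tagln, 0.93 for Myh11, 0.49 for Actg2, 0.40 for Vwf, -0.77 for Dcn and -1.05 for Igfbp7. Within macrophage markers, the difference was 0.83 for Aif1, -1.68 for Mrc1, -2.001 for Lyz2 and -2.19 for Csf1r. Regarding red blood cell markers, the difference was 0.40 for Bpgm. For epididymis markers, the difference was 0.29 for Cst8. Within ribosomal proteins, the difference was 0.69 for Rps24, 0.51 for Rps20, 0.25 for Rps15, 0.15 for Rpsa, -0.37 for Rpl13 and -1.72 for Rps14.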

How the results depend on the processing

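Total-count scaling and edgeR were chosen after the data were seen, and the other alternatives before. The counts of called genes in the 5 contrasts, and of genes changed in the same direction at both stages, stayed within 1.5 times under each alternative run, and Carm1 kept its directions and calls. DESeq2 called 4461 genes in round and 6418 in elongating spermatids, edgeR 7392 and 8008, and the fits on 4 libraries 6917 and 7823. Of the 8627 elongating calls, total-count scaling shared 6866, of which 5735 had the same direction, and the library sizes without the 50 most abundant genes shared 6828, of which 6009 had the same direction.

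Leaving out each library in turn, with the lone library assumed to vary like the other groups, gave 3359 to 5858 genes in round spermatids, 7369 to 8349 in elongating, 4655 to 6201 for the difference, 11892 to 13215 for the WT and 12412 to 13269 for the KO-labelled stage contrast, and 2098 to 3116 in the same direction at both stages. The lowest round count came without either round WT library. Carm1 ranged from -0.51 to -0.31 in round and from 0.83 to 0.91 in elongating spermatids, and the difference of its effects from 1.18 to 1.37. Lists past the threshold ranged from 8 to 9, 8 to 10, 5 to 6 and 12 to 12 for round, elongating, their difference and the WT stage contrast.

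With an estimated inter-gene correlation the 8, 8, 6 and 12 lists past the threshold became 0, 0, 0 and 4. In round spermatids the CREM-dependent, acrosome, flagellum and glycolysis lists had estimated correlations of 0.20, 0.026, 0.13 and 0.076, above the preset 0.01. The Sertoli, stress, ribosomal and macrophage lists had -0.022, -0.021, -0.017 and -0.009. These lie below the preset, so a higher correlation between genes does not account for their lost calls. The test with an estimated correlation also uses only the 4 residual degrees of freedom, which raises its p-values. A call lost there thus does not by itself show correlated genes. How much each part adds was not tested.

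Among named effects within a stage and in the WT stage contrast, scaling turned 9. Without the 50 most abundant genes and with total counts, Pabpc1 in round spermatids became -0.0130 and -0.0139. In elongating spermatids Prmt7 became -0.36 and -0.42, Ncoa2 -0.15 and -0.21, Bpgm -0.10 and -0.16 and Cst8 -0.11 and -0.18, and with total counts alone Hk1 became -0.000924 and Cypt2 -0.0452. In the WT stage contrast Gps2 became -0.0294 and -0.48, and Bpgm -0.44 with total counts. Of the differences between stages that passed for genes named in a knockout contrast, 13 turned without the 50 most abundant genes and 17 with total counts. In this order they became -0.0652 and -0.13 for Wwtr1, -0.12 and -0.19 for Fhl4, -0.0950 and -0.16 for Rfx4, -0.13 and -0.19 for Kdm3a, -0.0365 and -0.0994 for Cylc1, -0.0881 and -0.15 for Pgk2, -0.00917 and -0.0725 for Vwf, -0.0163 and -0.0791 for Bpgm, -0.16 and -0.22 for Rps15, -0.27 and -0.33 for Rpsa, -6.80e-05 and -0.0630 for Aldoart2, -0.18 and -0.24 for Ncoa2 and -0.12 and -0.18 for Cst8. With total counts alone they became -0.0199 for Tpi1, -0.0261 for Papolb, -0.0413 for Clu and -0.00730 for Dnajb1. The sizes of these changes follow from the shift of all genes that the scalings bring. The difference of Atf3 became 0.42 with a pseudocount of 10 and that of Psg19 0.18 with DESeq2, both genes with a group at 0 reads.

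Besides these, calls of named genes were lost by 24 with total counts, 22 without the 50 most abundant genes, 11 with DESeq2, 3 with edgeR, 3 with the fits on 4 libraries, 3 with the replicate block, 1 without a filter and 1 with each pseudocount, by 0 with TMM factors and by 0 of the 301 still tested at a mean of at least 50. Leaving out a library ended a call in 57 cases. Of the same differences between stages, calls were lost by 20 with total counts, 17 without the 50 most abundant genes, 9 with DESeq2, 6 with edgeR, 4 with the replicate block, 4 with a pseudocount of 0.5, 2 with TMM factors, 1 without a filter and 0 of the 130 still tested at a mean of at least 50, and in 78 cases on leaving out a library. The deviations between the libraries of a group correlated by -0.09 to 0.03 between groups over 8605 genes. No shared effect of the replicate numbers was seen, though this cannot show that same-numbered libraries share no animal or day. The block gave 4932, 8583 and 5718 calls for round, elongating and the difference of the knockout effect between stages. Depth limits genes with a group at few reads, where 3 counts correspond to 1.69 to 5.82 normalised counts per library.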

Other observations

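All tests of an explanation given here were chosen after the result was seen.

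The 25 tested lists were also compared with 10000 random lists matched on the WT stage ratio and on elongating WT level, by the median effect in elongating spermatids. The transcription regulators of spermatids, with a median of 0.44, lay above 99.95% of matched lists, with Spz1 at 0.68, Rfx2 at 0.80, Sox30 at 0.78 and Tcfl5 at 0.71 among 9 rises, and Tbpl1 at -0.85 and Gtf2a1l at -0.29 among 6 falls. This list did not pass its own test (camera adjusted p = 0.10, and adjusted p = 0.34 with an estimated correlation) and had 6 rises and 9 falls with total-count scaling. The stress genes (0.62) lay above 99.96%, Leydig markers (0.73) above 99.2%, multicopy genes (0.52) above 97.7%, the CREM-dependent genes (0.63) above 97.2%, and the histone exchange (0.28) above 50.8%. The Leydig list had 1 rise and 1 fall among 8 genes (camera adjusted p = 0.86) and the multicopy list 5 rises and 0 falls among 9 (adjusted p = 0.089), so neither passed its own test. The acrosome (-0.29) lay above 7.16%, Sertoli markers (-0.60) above 0.21% and macrophage markers (-1.19) above 0%, while the remaining lists lay between 5.36% and 89.9%. The transcription regulators and the stress, Leydig, multicopy, Sertoli and macrophage lists lay outside the middle 95% of their matched lists, with no adjustment for the number of lists. All others lay inside it, the CREM-dependent list just below its upper limit (0.631 against 0.636). The CREM-dependent, acrosome, histone, glycolysis and ubiquitin lists were thus not shown to stand apart from genes of like stage ratio. Lying inside the range does not show that they behave like those genes. Each library scaling moves a list and its matched lists alike.

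Of the 19 peritubular and vascular markers, 6 rose and 4 fell in elongating spermatids as deposited (camera adjusted p = 0.42, and adjusted p = 0.63 with an estimated correlation). Vwf went from 716 ± 8.79 to 1679 ± 36.4, Myh11 from 372 ± 38.9 to 1036 ± 46.8 and Actg2 from 19105 ± 435 to 33550 ± 902, while Pecam1, Cdh5, Lum and Sparc, chosen after their values were seen, were the members that fell. With total-count scaling this list had 5 rises and 11 falls. Among p53 targets Ccng1 went from 66.8 ± 1.44 to 29.7 ± 1.95, Sesn2 from 239 ± 7.33 to 123 ± 32.2 and Gadd45b from 30.5 ± 4.33 to 87.8 ± 11.8. Of the spermatogonia markers Stra8 fell from 50.1 ± 5.66 to 16.2 ± 3.73 and Sohlh2 rose from 99.2 ± 5.63 to 186 ± 28.1.

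Genes changed over 2-fold in the same direction at both stages, 472 with a position, gathered on some chromosomes: 6.27% of tested genes on chromosome 13, 5.19% on 12 and 5.05% on 7, against 1.33% on 8. Chance placement is argued against by a permutation p of 0.0001, the smallest that 10000 permutations can give. Thinning nearby genes to 1 per symbol root, the first letters of the symbol, and 1 per 100 kb left 425 genes. Their permutation p was again 0.0001, and 0.0005 for the 194 thinned genes at a log2 change of 1.5. This argues against overlapping neighbours and nearby families with a shared symbol root. Families under other symbols or farther apart stayed in, so they are not excluded. Whether DNA of another strain lies in blocks of the genome of one genotype cannot be told apart from other sources. Of all 472 genes, 52.1% had a neighbour in the set within 1 Mb, against 45.6% at random (permutation p = 0.012). In the thinned set the share was 44.7% against 40.6% (permutation p = 0.075). At a log2 change of 1.5 it was 42.3% against 25.6% before thinning (permutation p = 0.0001) and 33.5% against 22.4% after it (permutation p = 0.0021). Genes changed in elongating spermatids only did not gather on chromosomes (permutation p = 0.41). Within 10 Mb of Carm1 1 of 122 tested genes was in the set of 472 genes, against 30 of 871 (3.44%) on all of chromosome 9. A count this small cannot decide on strain DNA near Carm1. Such strain DNA may be one candidate source, and effects of the genotype stay open and untested.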
